A study of Mus musculus with 35 samples.

How the data were processed

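Total RNA from whole kidneys of FVB/NJ mice was extracted with TRIzol, and biotin-labelled cRNA from 5 ug of total RNA was hybridised to Affymetrix arrays, per the labels. The series holds 35 arrays, from diabetic OVE26 and control animals of 3 ages (2, 4 and 8 months). The deposited values are probe set summaries on a log2 scale, as their range shows, for 45101 probe sets on each array. The background correction, summarization and normalization methods are not given in the sources used here. The mean of the values differs between the 3 ages by more than within an age, while the medians of 2 and 8 months overlap, so the ages may have been scaled apart. Differences between diabetic and control arrays are therefore taken within an age.

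The arrays have no read depth, and the number of arrays per group limits the precision. The median SD within groups over all genes was 0.191 at 2 months, 0.120 at 4 months and 0.141 at 8 months. The Pearson r between 2 arrays of an age, across probe sets, lay between 0.969 and 0.998 at 2 months, 0.993 and 0.997 at 4 months, and 0.974 and 0.997 at 8 months. Array quality was followed with the 3'/5' log2 ratios of the beta-actin and Gapdh control probe sets.

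Of the probe sets, 34945 name 1 gene, 932 name several, 9160 name none and 64 are controls, and those with 1 gene were used. Symbols of 34741 of them matched the reference table by gene identifier, and 0 symbols changed. A gene was represented by its probe set with the highest mean over all 35 arrays, which gave 18193 genes. Genes with a mean log2 below 5.273, the 40th percentile of all probe sets, were left out, and 13004 were tested. Other probe sets were compared for 59 of the named genes, in 306 comparisons. Of 113 comparisons where the gene was called, 3 had the opposite sign, 0 of these called in the opposite direction. The other 110 had the same sign or, for Slc12a3 at 8 months and a probe set of Aqp6 at 4 months, stood at 0.00. Only the sign was compared, and the sizes could differ. Of 193 comparisons where the gene was not called, the other probe set was called in 4, 2 for Pck1 and 2 for Igha.

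A mean per group was fitted to each gene over all 35 arrays with limma 3.58.1 on R 4.3.3, with the data.table package, version 1.17.8. The fit had 29 residual degrees of freedom and 33.7 with the moderation of the variances. Contrasts were the diabetic minus the control mean at each age, the differences of these between ages with an F test over them, and 8 against 2 months within each group. A gene is called when its two-sided p, adjusted by Benjamini and Hochberg over the 13004 genes, is under 0.05. Errors after a log2 difference are standard errors of the limma fit, and errors after a group mean are standard deviations. The fit takes a single spread per gene over all groups. Its standard errors and p therefore tend to be too small where the compared groups vary more than the others. Where they vary less, these tend to be too large.

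The comparisons, the 34 gene lists with 558 genes, the rule for the named genes and a set of other ways to process the values were fixed before the data were examined. Lists were tested with camera of limma, with an inter-gene correlation of 0.01, against the other genes tested and adjusted over the 34 lists of a contrast. Beside it stand the same test with a correlation estimated for each list, and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes. With an estimated correlation 0 lists were called at 2 months, 1 at 4 months and 2 at 8 months, and fry called 1, 2 and 20. Members of a list were also adjusted over the list alone. Cell type markers were treated as lists, and no cell types were called from whole-kidney RNA.

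The named genes are, for each diabetes effect, the 8 largest positive and 8 largest negative differences among called genes without overlap between the arrays of the groups. To these come up to 3 genes of each list with the smallest p at any age, and the 5 largest positive and negative changes among called genes for each change with age. Names of the Gm-number, LOC, Rik and cDNA forms were passed over. A set of 20 genes was to be named whatever their result, and of these 15 were tested (Txnip, Slc5a2, Pck1, G6pc, Havcr1, Lcn2, Nphs1, Vegfa, Tgfb1, Ccn2, Col1a1, Col3a1, Fn1, Umod and Egf). The others were not analysed here. Heat-shock genes, targets of p53 and a few more genes in the last part were chosen after their values were seen.

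Same-numbered diabetic and control arrays could be pairs, which the labels do not say. After removing the group means, same-numbered arrays were correlated at 2 months, with r from 0.246 to 0.444 in 6 of 6 pairs. Of the 12 arrays of that age 7 correlated best with the array of their own number. At 4 months r lay between 0.0484 and 0.177, with 1 of 4 pairs above 0.1, and at 8 months between -0.142 and 0.234, with 2 of 6 above 0.1. A fit with blocks of replicate number within age is given beside the 2-month result.

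Chosen beforehand as other ways to process the values were quantile normalization, centring of each array on its median, no filter and a filter at the 60th percentile (6.597), the mean of all probe sets of a gene, a fit of the groups of a comparison alone, a trended and robust variance model, array quality weights, the replicate block, the 3'/5' ratio as a covariate, stricter thresholds and leaving out each array in turn. Those chosen after seeing the data were quantile normalization within each age, arrays scaled to one mean and spread, the difference of Arntl and Dbp per array as a covariate for the clock, the 2-month arrays 5 and 6 as a batch, alone or left out, the fit without 4-month controls 3 and 4, and the block together with an estimated correlation. Up to 100 random splits of the same arrays into groups of the same sizes were drawn with a fixed seed for each comparison.

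The fit was tested on simulated data of 13004 genes with the group sizes of the arrays. For the diabetes effect at 2 months it recovered 80.6% of genes changed by log2 0.5, 92.5% of those changed by 1 and 100% of those changed by 2, and 3.19% of its calls were unchanged genes. For that at 4 months the shares were 76.1%, 97% and 98.5%, with 7.18% false, and for that at 8 months 74.6%, 100% and 100%, with 5.67% false. For the change from 2 to 8 months 333 of 395 changed genes were recovered and 11 unchanged genes called. A simulated list of 24 genes shifted by 0.5 at 8 months was called, and 0 of 33 others. The simulated genes were drawn independently of each other and without any structure among the arrays. Each gene also had the same spread on all arrays, as the fit assumes, while the real spread differed between ages. These shares therefore do not measure false calls of genes or lists that come from correlated genes or from such structure. Nor do they measure calls made or missed because the spread differs between groups.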

Results

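Whole-kidney RNA from FVB/NJ mice was measured on 35 Affymetrix arrays from animals aged 2, 4 or 8 months. The diabetic mice were of the OVE26 line, in which extra calmodulin in the pancreatic beta cells causes insulin deficiency from early life. There were 6 diabetic and 6 control arrays at 2 months, 7 diabetic and 4 control arrays at 4 months, and 6 diabetic and 6 control arrays at 8 months. The values are log2 signals, and 13004 genes passed the filter on dim probe sets. An array has no read depth, so the number of arrays per group limits the precision. Xist, which is transcribed from the inactive X chromosome, had a signal of at least 10.11 on every array, and no Y-linked gene exceeded 4.92. No pair of arrays was identical. Values below are log2 differences, diabetic minus control, ± SE of the model, and the gene positions in a genome are not given.

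The comparison at 2 months concerned the youngest mice. Hspa1a, an inducible heat-shock chaperone, rose by 2.15 ± 0.35, or 4.44-fold, from a mean of 7.64 ± 0.20 (SD, n = 6) in controls to 9.79 ± 0.89 (SD, n = 6) in diabetic kidneys, with an adjusted p of 0.000385. Its near duplicate Hspa1b rose by 1.52 ± 0.23, and the co-chaperone Dnaja1 by 0.75 ± 0.12. Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 1.27 ± 0.25, and Npl, a sialic acid lyase, by 0.78 ± 0.13. Mfsd2a, a transporter of lysophospholipids, fell by 1.74 ± 0.22 with an adjusted p of 1.24e-05. Mdk, the growth factor midkine, fell by 1.05 ± 0.15, Acot7, an acyl-CoA thioesterase, by 1.08 ± 0.17, and the sodium-proton exchanger gene Slc9a8 by 1.10 ± 0.18. In these 9 genes each of the 6 diabetic arrays lay on the same side of all 6 control arrays.

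Across all genes tested at 2 months, 98 rose and 232 fell, 330 in all, and 17 of these changed at least 2-fold. The groups did not overlap for 195 genes, 127 of them called, where chance gives 0.216% of genes. Other genes without overlap were Mtarc1 (1.59 ± 0.42), Slc43a2 (0.73 ± 0.15) and Tmem52 (0.61 ± 0.17) among those that rose. Among those that fell they were Tle2 (-1.33 ± 0.19), Rnf24 (-1.21 ± 0.28), Pcolce2 (-1.06 ± 0.21) and Serpina10 (-1.04 ± 0.27). Dimmer probe sets were called for Hspa1b (1.90 and 1.65) and Dnaja1 (0.43, with another at 0.27 not called). They were not called for Cdkn1a (0.38), Mtarc1 (0.12), Rnf24 (-0.04), Slc9a8 (-0.32 and -0.27) and Slc43a2 (0.26 and 0.76).

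Of the 11 thick ascending limb genes measured, 0 rose and 2 fell at 2 months (0 and 5 adjusted over the list alone), with a median of -0.26 and an adjusted p of 8.99e-05 in the list test. The 2 that fell were Umod, the gene for uromodulin (-0.19 ± 0.05), and the prostaglandin receptor Ptger3 (-0.58 ± 0.15). The list test gave an adjusted p = 0.555 with an estimated correlation. Of 9 principal cell genes, 1 fell (1 adjusted over the list alone), the water channel Aqp4 (-0.69 ± 0.17). The list test called the principal cell genes lower, with a median of -0.16 (adjusted p = 0.0288; adjusted p = 0.555 with an estimated correlation). That call was also lost with arrays 5 and 6 as a batch term (adjusted p = 0.0558) and with the mean of all probe sets of a gene (adjusted p = 0.053). Of 9 genes of gluconeogenesis and ammoniagenesis, 1 rose (4 adjusted over the list alone), the glutamine transporter Slc38a3 (0.80 ± 0.19), with a median of 0.15 (adjusted p = 0.00317; adjusted p = 0.555 with an estimated correlation).

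No member passed, over all genes or adjusted over the list alone, in 3 lists that the list test called higher at 2 months. The 27 genes of fatty acid oxidation and PPAR-alpha targets had a median of 0.17 (adjusted p = 0.00347), the 23 fibroblast and extracellular matrix genes one of 0.25 (adjusted p = 0.0034) and the 13 cell cycle genes one of 0.30 (adjusted p = 0.0109). Each of these 3 had an adjusted p = 0.858 with an estimated correlation. Single members of other lists also passed. Ephx1, a detoxifying epoxide hydrolase, rose by 0.59 ± 0.10 and the endoplasmic reticulum chaperone gene Dnajb9 by 0.52 ± 0.11, while Dnajc3 fell by 0.41 ± 0.08, Cyp4b1 by 0.56 ± 0.15 and Mme, the gene for neprilysin, by 0.27 ± 0.07. A dimmer probe set of Mme stood at 0.21 (adjusted p = 0.763).

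At 2 months the arrays numbered 5 and 6 in both groups stood apart on the first principal component, which held 42.8% of the variance. They scored from -36.6 to -9.32 there, while arrays 1 to 4 scored from 7.18 to 14.1. Control 6 also had a beta-actin 3'/5' log2 ratio of 2.56, where the other arrays of that age had at most 1.35. Clock genes were not balanced between the groups. Diabetic 1, 5 and 6 had Arntl at 7.80, 7.88 and 8.28 and Dbp at 9.29, 8.26 and 7.95. Control 6 had 7.66 and 8.87, while all other 2-month arrays lay from 6.52 to 6.82 for Arntl and 10.14 to 11.62 for Dbp. With the clock covariate 23 of the 25 named genes were called. Arrays 1 to 4 alone gave 341 genes, 174 of them among the 330. Arrays 5 and 6 alone gave 571 genes, 111 of them among the 330, and a term for these arrays as a batch gave 696. Same-numbered arrays of the 2 groups were correlated at 2 months, and with the replicate number as a block 553 genes were called, 168 higher and 385 lower, including 305 of the 330. The 25 genes and 6 lists named at 2 months were all called in that blocked fit too. Of the 25 genes, 19 were called with arrays 1 to 4 alone, 6 with arrays 5 and 6 alone, and 14 in a fit of the 2-month arrays alone. The count was 515 without diabetic array 2, 512 without control array 5, 219 without control array 1 and 192 without control array 2. It was 64 in a fit of the 2-month arrays alone, which does not share the estimate of the spread with the other ages. The median SD within groups was 0.191 at 2 months, against 0.120 at 4 months and 0.141 at 8 months. Mtarc1, Tmem52, Serpina10, Umod, Slc38a3, Ptger3, Aqp4, Cyp4b1 and Mme each missed the threshold without at least 1 of the 12 arrays, and 16 of the 25 named genes passed without any 1 of them.

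**Figure D1:**
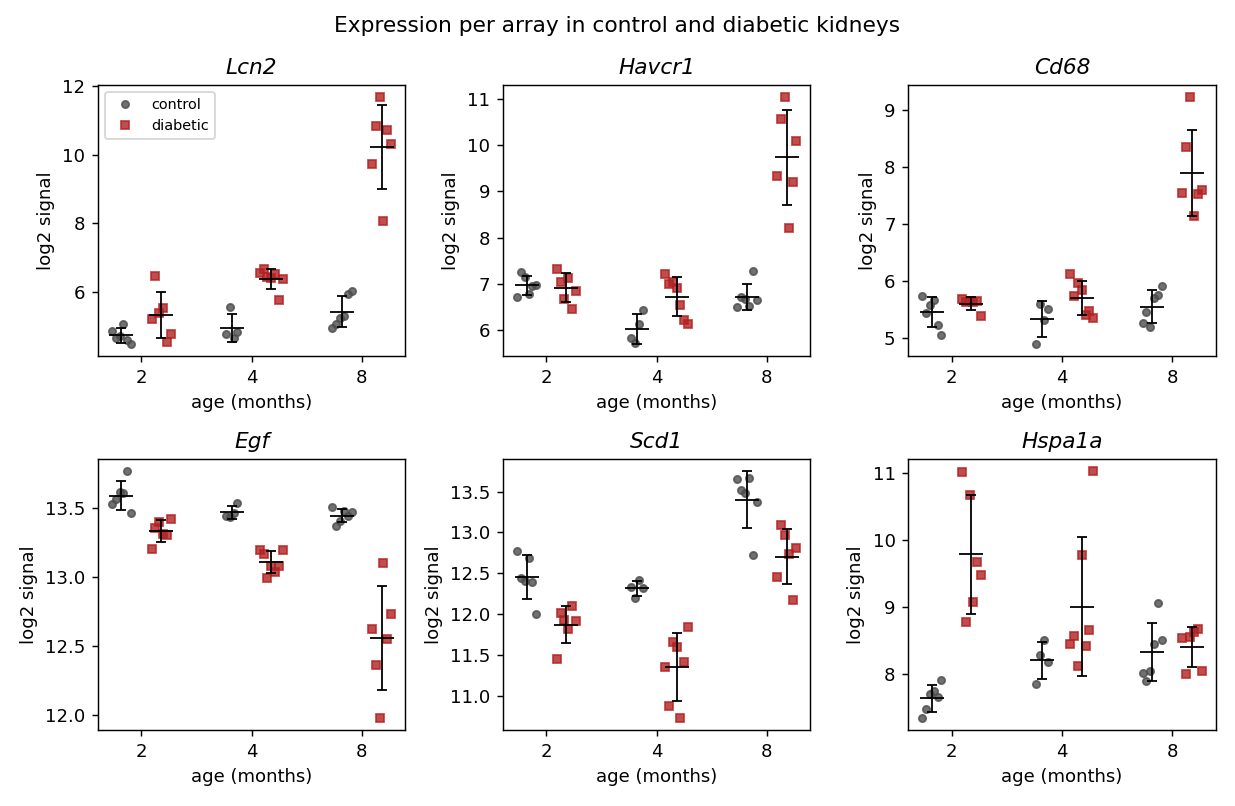
Log2 signal of Lcn2, Havcr1, Cd68, Egf, Scd1 and Hspa1a on each array against age in months; circles are control arrays, squares diabetic arrays, and black bars the mean ± SD of each group. Lcn2 stood at 10.22 in diabetic and 5.43 in control kidneys at 8 months, and Hspa1a at 9.79 and 7.64 at 2 months.

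At 4 months the comparison had 7 diabetic and 4 control arrays. The chemokine gene Cxcl10 rose by 1.35 ± 0.21, or 2.55-fold (adjusted p = 0.000864), from 5.89 ± 0.19 (SD, n = 4) in controls to 7.24 ± 0.41 (SD, n = 7) in diabetic kidneys. Rcan1, an inhibitor of calcineurin, rose by 1.15 ± 0.19, and Slco4c1, an organic anion transporter, by 1.33 ± 0.24. Anxa13, an annexin, fell by 1.56 ± 0.25, or 2.95-fold (adjusted p = 0.000864). Slc9a8 and Mdk each fell by 1.06, with SEs of 0.19 and 0.17. Scd1, a desaturase that makes monounsaturated fatty acids, fell by 0.96 ± 0.19. In these 7 genes no diabetic array overlapped the control arrays.

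Over all genes at 4 months, 54 rose and 72 fell, 126 in all, and 18 changed at least 2-fold. The groups did not overlap for 625 genes, 101 of them called, where chance gives 0.606% of genes. The share of called genes that rose was 42.9% as deposited. It was 55% after quantile normalization (71 higher, 58 lower), 53.6% with that done within each age (75 higher, 65 lower), and 54.5% with arrays scaled to one mean and spread (48 higher, 40 lower). Cyp4a12a (1.85 ± 0.36), Aldh1a7 (1.55 ± 0.31), the nuclear receptor gene Nr4a1 (1.41 ± 0.32), the metallothionein gene Mt2 (1.33 ± 0.32) and Reep6 (1.29 ± 0.26) also rose without overlap. Spidr (-1.37 ± 0.30), Akr1c20 (from 7.78 in controls to 6.78), Egfl6 (-0.98 ± 0.21) and C1qtnf3 (-0.88 ± 0.21) fell without overlap.

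Fatty acid synthesis was the gene list with the smallest adjusted p of the list test at 4 months (3.65e-10). Of its 15 genes, 0 rose and 3 fell (0 and 9 adjusted over the list alone), with a median of -0.39. The 3 were Scd1, the fatty acid synthase gene Fasn (-0.99 ± 0.23) and the acetyl-CoA carboxylase gene Acaca (-0.65 ± 0.13). The list kept its call with an adjusted p = 2.18e-05 with an estimated correlation. With the mean of all probe sets of a gene its median was -0.24, and it was still called (adjusted p of the list test = 1.27e-09). The 11 thick ascending limb genes had a median of -0.29, and 0 fell over all genes (8 adjusted over the list alone; adjusted p of the list test = 3.39e-07; adjusted p = 0.104 with an estimated correlation). Of 11 intercalated cell genes, 2 fell (6 adjusted over the list alone), the anion exchanger gene Slc26a4 (-0.51 ± 0.11) and Aqp6 (-0.35 ± 0.08). The intercalated cell median was -0.35 (adjusted p = 4.75e-07; adjusted p = 0.199 with an estimated correlation). Of 12 podocyte genes, 1 fell (2 adjusted over the list alone), Thsd7a (-0.59 ± 0.15), with a median of -0.14 (adjusted p = 0.00745; adjusted p = 0.314 with an estimated correlation). The 19 cholesterol synthesis genes had a median of -0.15 with 0 passing either way (adjusted p = 0.00427; adjusted p = 0.539 with an estimated correlation). With the replicate block this median was -0.09 and the call was lost (adjusted p = 0.117).

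Among lists called higher at 4 months, 1 of 24 tubular injury genes rose (4 adjusted over the list alone), with a median of 0.34 and an adjusted p of 1.59e-06. The 1 was the keratin gene Krt18 (0.60), named after its value was seen. The median of 10 immediate early genes was 0.69 (adjusted p = 4.22e-05), with 1 rising (1 adjusted over the list alone), Nr4a1. For 22 antioxidant genes the median was 0.11 (adjusted p = 0.00364), with 3 rising (4 adjusted over the list alone), Mt2, Ephx1 (0.68 ± 0.11) and Mt1 (0.84, named after its value was seen). The clock list of 13 genes had a median of 0.33 and 0 passing (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.0253). Each of these 4 lists had an adjusted p = 0.314 with an estimated correlation. No member passed in the lists for the cell cycle (median 0.47; adjusted p = 0.000404; adjusted p = 0.539 with an estimated correlation) and for fatty acid oxidation and PPAR-alpha targets (median 0.18; adjusted p = 0.00382; adjusted p = 0.737 with an estimated correlation). Both counts were 0 adjusted over the list alone as well. With the clock covariate the antioxidant (adjusted p = 0.0757) and fatty acid oxidation and PPAR-alpha target (adjusted p = 0.157) calls were lost and the clock list turned to -0.05, and with the mean of all probe sets of a gene the clock call was lost (adjusted p = 0.0607). Aqp4 fell by 0.74 ± 0.18, and the hypoxia gene Egln3 rose by 0.63 ± 0.15. Lcn2, the gene for neutrophil gelatinase-associated lipocalin, stood at 1.43 ± 0.38 and missed the threshold (adjusted p = 0.0552). Its 4-month groups did not overlap, with diabetic arrays from 5.775 to 6.666 and controls from 4.662 to 5.579. The SE uses a spread shared with the 8-month diabetic arrays, which ran from 8.068 to 11.668.

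Controls 3 and 4 stood apart from the other 4-month arrays in 2 clock genes and over all genes, at -18.0 and -18.6 on the first principal component (29.4% of the variance), where the others lay from -6.24 to 13.1. Their Arntl signals were 7.84 and 8.17 and their Dbp signals 8.75 and 8.02, while the other 9 arrays lay at or below 6.21 for Arntl and at or above 10.24 for Dbp. Without both of them 5 genes were called, and the count was 29 without control 4, 36 without control 3 and 78 without diabetic array 5. A fit of the 4-month arrays alone called 358 genes. Cxcl10, Slco4c1, Rcan1, Anxa13, Slc9a8, Mdk, Scd1, Acaca and Ephx1 passed without any 1 of the 11 arrays, and the other 15 of the 24 named genes missed the threshold without at least 1 of them.

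At 8 months the kidneys of the oldest mice were compared. Lcn2, a secreted marker of tubular injury, rose by 4.79 ± 0.35, or 27.6-fold, from 5.43 ± 0.45 (SD, n = 6) to 10.22 ± 1.23 (SD, n = 6), with an adjusted p of 2.55e-11. The SE uses a spread shared by all groups, while diabetic kidneys varied more here, so the SE and p can understate the error. Havcr1, the gene for kidney injury molecule 1, rose 8.04-fold (3.01 ± 0.28), and Cd44, an adhesion receptor, 7.42-fold (2.89 ± 0.26). For Havcr1 too the diabetic arrays varied more, from 8.210 to 11.031 against 6.503 to 7.279 in controls. The lysozyme genes Lyz2 and Lyz1 rose by 2.69 ± 0.23 and 2.41 ± 0.21, and Ighm, the gene for the immunoglobulin M heavy chain, by 2.52 ± 0.21. Ubd, a ubiquitin-like gene, rose by 3.37 ± 0.40, and Cyp27b1, the enzyme that makes active vitamin D, by 2.95 ± 0.45. Each of these 8 genes was higher in all 6 diabetic arrays than in any control array.

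Genes that fell furthest at 8 months without overlap were Ucp1, the uncoupling protein of brown fat (-2.20 ± 0.46), Egfl6 (-1.69 ± 0.20), Anxa13 (-1.66 ± 0.23), the organic anion transporter gene Slc22a26 (-1.52 ± 0.35), Nap1l5 (-1.50 ± 0.18), the kidney androgen-regulated gene Kap (-1.49 ± 0.40), Pvalb (-1.38 ± 0.24) and the endothelial gene Esm1 (-1.36 ± 0.17). Over all genes 1283 rose and 904 fell, 2187 in all, and 163 changed at least 2-fold. The groups did not overlap for 1261 genes, 1052 of them called, where chance gives 0.216%.

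Of 24 tubular injury genes, 23 rose at 8 months (24 adjusted over the list alone), with a median of 1.17 (adjusted p of the list test = 1.19e-32). The list kept its call with an estimated correlation (adjusted p = 0.00547) but not with that and the replicate block (adjusted p = 0.1). Macrophage and dendritic cell genes rose in 21 of 23 cases (21 adjusted over the list alone), with a median of 0.98. Examples were Cd68 (2.35 ± 0.21) and Ms4a7 (2.10 ± 0.19). The adjusted p of the list test was 6.94e-22, and the adjusted p = 0.0504 with an estimated correlation. Of 12 lymphocyte and plasma cell genes, 9 rose (9 adjusted over the list alone), with a median of 0.80, among them Mzb1 (1.27 ± 0.15) and Coro1a (1.35 ± 0.18); the adjusted p was 7.14e-08, and adjusted p = 0.0719 with an estimated correlation. Of 21 genes of interferon response and antigen presentation, 17 rose (17 adjusted over the list alone), with a median of 0.70, among them Cxcl10 (2.21 ± 0.20), Bst2 (1.10 ± 0.17) and Oas1a (0.84 ± 0.14). Their adjusted p was 1.75e-11, and adjusted p = 0.155 with an estimated correlation. Complement genes went both ways, with 4 of 9 higher and 2 lower (5 and 2 adjusted over the list alone), a median of 0.41 and an adjusted p of 0.133. Cfi rose by 1.18 ± 0.26 and Masp1 by 0.67 ± 0.11, while Cfb fell by 0.40 ± 0.08. C1ra (0.53) and C1s1 (0.51), which rose, and C2 (-0.30), which fell, were named after their values were seen.

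Of 23 fibroblast and extracellular matrix genes, 14 rose at 8 months (17 adjusted over the list alone), with a median of 0.66. They included the collagen genes Col1a1 (1.61 ± 0.33), Col3a1 (1.64 ± 0.39), Col5a2 (1.31 ± 0.24) and Col4a2 (0.77 ± 0.13), and Vim, the gene for vimentin (0.89 ± 0.15). In the list test their adjusted p was 1.18e-09, and adjusted p = 0.257 with an estimated correlation. The fibronectin gene Fn1 stood at 0.52 ± 0.24 and missed the threshold (adjusted p = 0.151). It ran from 0.22 without diabetic array 3 to 0.72 without diabetic array 5, where Fn1 was called (adjusted p = 0.0327). Of 14 TGF-beta response genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.015; adjusted p = 0.357 with an estimated correlation). Tgfb1 rose by 0.68 ± 0.12 and Tgfbi by 0.95 ± 0.16, while Smad7, an inhibitor of the pathway, fell by 0.46 ± 0.08. Ccn2, a matricellular gene of the same list, stood at 0.53 ± 0.20 (adjusted p = 0.0713). Ccn2 ran from 0.35 without diabetic array 3 to 0.70 without diabetic array 6, where it was called. Of 10 smooth muscle, mesangial and renin cell genes, 5 rose (8 higher and 1 lower adjusted over the list alone), with a median of 0.27 (adjusted p = 0.000429; adjusted p = 0.188 with an estimated correlation). They were the smooth muscle genes Acta2 (0.92 ± 0.15) and Tagln (1.06 ± 0.19), the receptor gene Pdgfrb (0.59 ± 0.17), and Mcam (0.48) and Cspg4 (0.19), these last named after their values were seen.

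Of 11 thick ascending limb genes, 9 fell at 8 months (9 adjusted over the list alone), with a median of -0.37 (adjusted p = 1.27e-07; adjusted p = 0.0504 with an estimated correlation). Egf, the gene for epidermal growth factor, fell by 0.89 ± 0.10, Wfdc15b by 1.29 ± 0.14, Tmem207 by 1.03 ± 0.17 and Umod by 0.29 ± 0.05. Egf was not called at 2 or 4 months, though its groups did not overlap there. Its diabetic arrays reached at most 13.419 at 2 months and 13.200 at 4 months, and controls lay at or above 13.463 and 13.434. Of 8 distal convoluted and connecting tubule genes, 6 fell (7 adjusted over the list alone), with a median of -0.51 (adjusted p = 1.94e-06; adjusted p = 0.0504 with an estimated correlation). Pvalb, the thiazide-sensitive cotransporter gene Slc12a3 (-0.77 ± 0.12) and the sodium-calcium exchanger gene Slc8a1 (-1.06 ± 0.19) were among them. Of 11 intercalated cell genes, 7 fell (8 adjusted over the list alone), with a median of -0.39, among them Slc26a4 (-0.77 ± 0.10), Aqp6 (-0.47 ± 0.08) and the homeobox gene Hmx2 (-0.78 ± 0.18). Their adjusted p was 3.34e-06, and adjusted p = 0.154 with an estimated correlation. Of 26 proximal tubule genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.18 (adjusted p = 3.55e-05; adjusted p = 0.257 with an estimated correlation). With the clock covariate the proximal tubule median was -0.11. The organic anion transporter gene Slc22a7 fell by 1.18 ± 0.21, the glucose transporter gene Slc5a2 by 0.46 ± 0.09 and the inositol oxygenase gene Miox by 0.44 ± 0.10, while the glucose transporter gene Slc2a2 rose by 0.56 ± 0.14. Principal cell genes had a median of 0.09 (adjusted p = 0.529), with Aqp2 (0.66 ± 0.18) and Aqp3 (0.49, named after its value was seen) the 2 that rose and Aqp4 the 1 that fell (-0.72 ± 0.17). The counts adjusted over the list alone were 2 and 1.

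In the glomerulus and vessels at 8 months, 5 of 12 podocyte genes fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.0426; adjusted p = 0.357 with an estimated correlation). The podocyte call was also lost with the replicate block (adjusted p = 0.0774), the mean of all probe sets of a gene (0.116) and the clock covariate (0.0622). The slit diaphragm gene Nphs1 fell by 0.61 ± 0.12 and the podocyte phosphatase gene Ptpro by 0.52 ± 0.09. The others, named after their values were seen, were Tcf21 (-0.45), Dach1 (-0.30) and Plce1 (-0.25), which fell, and Cd2ap (0.28), which rose. Of 17 endothelial genes, 1 fell (1 adjusted over the list alone), Cldn5 (-0.33 ± 0.10), with a median of 0.02 (adjusted p = 0.899). Markers of neighbouring tissue did not pass as lists. The medians were 0.39 for 3 adipose genes (0 called, 0 adjusted over the list alone; adjusted p = 0.6), -0.05 for 2 adrenal cortex genes (0 called, 0 adjusted over the list alone; adjusted p = 0.607) and 0.63 for 2 red cell genes (adjusted p = 0.121). Of the red cell genes 1 rose (2 adjusted over the list alone), Slc25a37 (0.32 ± 0.11).

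Fatty acid synthesis was again lower at 8 months. Of its 15 genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone), with a median of -0.38 (adjusted p = 6.03e-07). The list kept its call with an adjusted p = 0.00106 with an estimated correlation. Scd1 fell by 0.70 ± 0.17, Acaca by 0.55 ± 0.12 and the elongase gene Elovl6 by 0.43 ± 0.08, where a dimmer probe set of Elovl6 stood at 0.27 (adjusted p = 0.291). Of 19 cholesterol synthesis genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.0426; adjusted p = 0.481 with an estimated correlation). That call was also lost with the clock covariate (median -0.12; adjusted p = 0.059). Cyp51, a sterol demethylase gene, fell by 0.48 ± 0.12 and the sterol regulator gene Srebf2 by 0.36 ± 0.08. Insig1 (-0.53) and Stard4 (-0.41), which fell, and Sqle (0.48), which rose, were named after their values were seen. Of 27 genes of fatty acid oxidation and PPAR-alpha targets, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.0426; adjusted p = 0.677 with an estimated correlation). The lipase inhibitor gene Angptl4 rose by 2.05 ± 0.53 and the lipid droplet gene Plin2 by 0.76 ± 0.16, while Acadm, an enzyme of beta-oxidation itself, fell by 0.28 ± 0.09. Of 32 genes of oxidative phosphorylation, 3 fell (3 adjusted over the list alone), Sdha (-0.25 ± 0.06), Sdhb (-0.17 ± 0.05) and Cox6c (-0.15, named after its value was seen). Their median was -0.08 (adjusted p = 0.00156; adjusted p = 0.431 with an estimated correlation).

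Glucose-related lists did not pass as lists at 8 months. Of 9 genes of gluconeogenesis and ammoniagenesis, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.434). Slc38a3 rose by 0.98 ± 0.19 and Slc2a2 by 0.56 ± 0.14, while Ppargc1a (-0.33, named after its value was seen) fell. Pck1, the gene for the rate-limiting enzyme of gluconeogenesis, stood at -0.02 ± 0.08 (adjusted p = 0.896) and G6pc, the glucose-6-phosphatase gene, at -0.09 ± 0.11 (adjusted p = 0.637). The probe sets of Pck1 disagreed: a dimmer one was called lower at 8 months (-1.11; adjusted p = 3.06e-05) and at 4 months (-0.80; adjusted p = 0.0374), and another stood at 0.01 at 8 months (adjusted p = 0.987). Of 12 genes of the glucose response, polyol and hexosamine pathways, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.115). Arrdc4 rose by 0.82 ± 0.15, the aldose reductase-like gene Akr1b8 by 0.81 ± 0.13, Slc2a2 as above and Slc5a1 by 0.38 (named after its value was seen), and Slc5a2 fell, while the glucose-responsive gene Txnip stood at 0.36 ± 0.26 (adjusted p = 0.386). Of 12 glycolysis genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.163). Pfkp rose by 0.48 ± 0.11 and Tpi1 by 0.17 ± 0.06, while Pfkm fell by 0.32 ± 0.07.

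Of 22 antioxidant genes, 5 rose at 8 months (5 adjusted over the list alone), with a median of 0.07 (adjusted p = 0.0532). The haem oxygenase gene Hmox1 rose by 1.94 ± 0.46, Ephx1 by 0.83 ± 0.10 and the sulfiredoxin gene Srxn1 by 0.68 ± 0.13. Nqo1 (0.55) and Txnrd1 (0.19) were named after their values were seen. Of 15 unfolded protein response genes, 3 rose (3 adjusted over the list alone), the asparagine synthetase gene Asns (0.94 ± 0.13), Dnajb9 (0.34) and Hspa5 (0.57, named after its value was seen), with a median of 0.14 (adjusted p = 0.0122; adjusted p = 0.271 with an estimated correlation). Of 13 cell cycle genes, 5 rose (9 adjusted over the list alone), with a median of 0.74 (adjusted p = 9.6e-05; adjusted p = 0.357 with an estimated correlation). They were the replication helicase genes Mcm3 (0.49 ± 0.14), Mcm5 (1.11 ± 0.33) and Mcm6 (1.15 ± 0.32), and Mki67 (0.94) and Rrm2 (0.87), these last named after their values were seen.

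No list call was made at 8 months for the remaining lists. Of 8 hypoxia genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of -0.01, a mean of 0.12 and a list test that pointed up (adjusted p = 0.728). Adm, the adrenomedullin gene, rose by 0.86 ± 0.22 and Egln3 by 0.45 ± 0.14, while Vegfa, the gene for vascular endothelial growth factor A, fell by 0.38 ± 0.09. Of 6 genes of the renin-angiotensin system, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.369). The angiotensinogen gene Agt rose by 0.88 ± 0.17, while Ace, the angiotensin-converting enzyme gene, fell by 0.54 ± 0.13 and Mme by 0.39 ± 0.07. Of 20 Wnt pathway genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone), with a median of -0.08 (adjusted p = 0.236), and the 3 were the inhibitor genes Sfrp1 (-0.78 ± 0.16), Sfrp2 (-0.55 ± 0.14) and Rnf43 (-0.28 ± 0.07). The 1 that rose was Mmp7 (0.31), named after its value was seen. Of 8 androgen-dependent kidney genes, 2 fell (2 adjusted over the list alone), Kap and Cyp4b1 (-0.51 ± 0.15), with a median of -0.17 (adjusted p = 0.136). Of 13 clock genes, 2 fell (2 adjusted over the list alone), Per3 (-0.76 ± 0.22) and Tef (-0.42 ± 0.14), with a median of -0.20 (adjusted p = 0.149). At this age diabetic arrays 1, 2 and 5 had Dbp signals of 8.25, 8.14 and 7.32, where the other 9 arrays lay from 9.48 to 10.88. With the clock covariate Per3 was still called (-0.46) and Tef was not (-0.25). Of 10 immediate early genes, 1 rose (1 adjusted over the list alone), Atf3 (1.57 ± 0.26), with a median of 0.17 (adjusted p = 0.217).

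The 8-month count stayed between 1633 and 2329 when each of the 12 arrays was left out in turn. Diabetic array 3, without which it was 1633, stood apart on the first principal component (48.4% of the variance), at 39.0 where the other diabetic arrays lay from 3.00 to 17.0. Of 96 called genes selected for the text at this age, 85 passed without any 1 array, and Cldn5, Pdgfrb, Acadm, Tpi1, Sdhb, Mcm5, Egln3, Cyp4b1, Per3, Tef and Slc25a37 missed the threshold without at least 1 of them. In a fit of the 8-month arrays alone, with their own spread, 92 of the 96 were called.

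**Figure D2:**
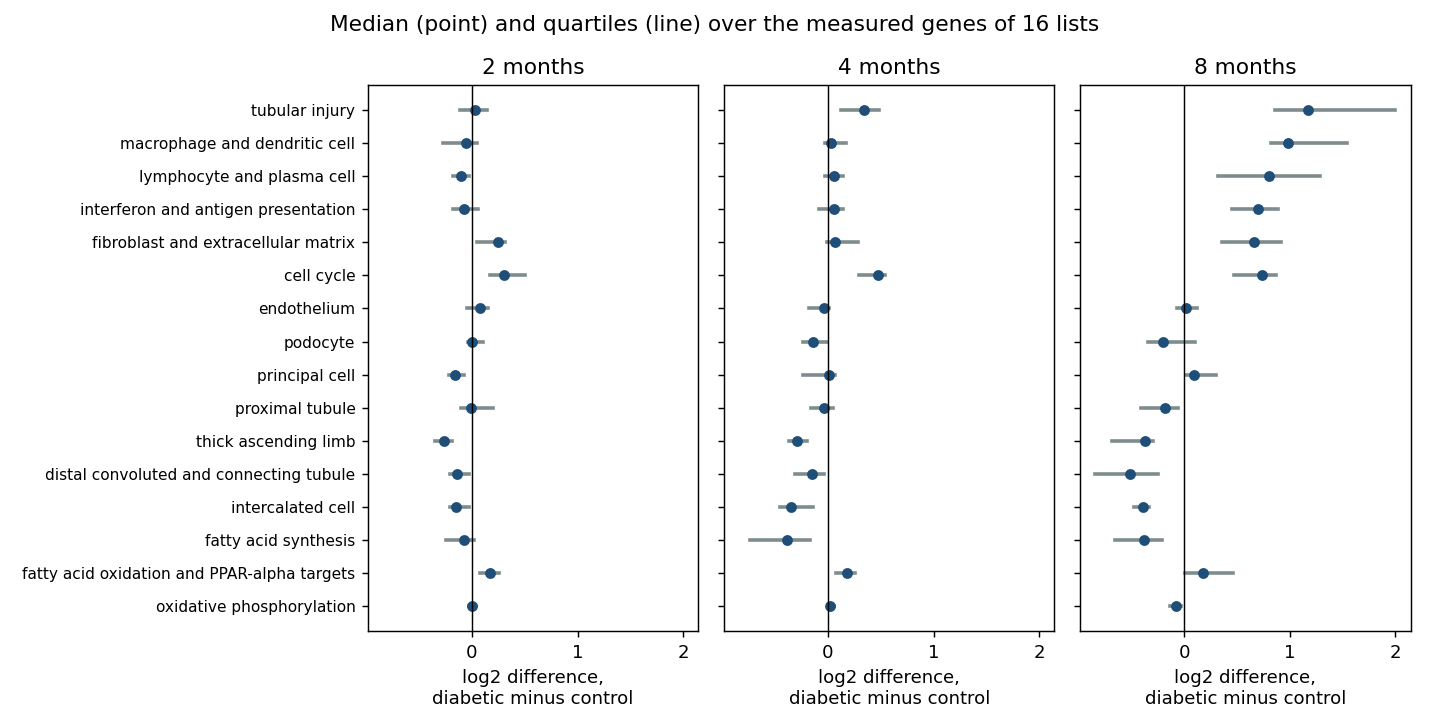
Median (point) and quartiles (line) of the log2 difference, diabetic minus control, over the measured genes of 16 lists, with 1 panel per age. The tubular injury median was 0.03 at 2 months, 0.34 at 4 months and 1.17 at 8 months, and the fatty acid synthesis median was -0.07, -0.39 and -0.38.

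Some genes were called at every age. There were 45, of which 13 rose and 32 fell at all 3 ages. At 2, 4 and 8 months Mdk fell (-1.05, -1.06 and -1.12), as did Slc9a8 (-1.10, -1.06 and -1.30) and Aqp4 (-0.69, -0.74 and -0.72). Ephx1 rose by 0.59, 0.68 and 0.83, and Mtarc1 by 1.59, 1.96 and 1.78. A dimmer probe set of Mtarc1 stood at 0.12, 0.39 and 0.25 and was not called at any age. Of the genes that rose, 13 were shared by 2 and 4 months, where 0.407 would be shared if the calls were independent, 39 by 2 and 8 months (9.67) and 43 by 4 and 8 months (5.33). Of those that fell, 34 were shared by 2 and 4 months (1.28), 103 by 2 and 8 months (16.1) and 57 by 4 and 8 months (5.01). Only 2 genes were called in opposite directions at any pair of ages, both at 2 and 8 months: Serpina10 (-1.04 and 2.12) and Abtb2 (-0.39 and 0.28), the latter named after its values were seen. Of the 330 genes called at 2 months, 291 (88.2%) had the same sign at 8 months, as did 121 of the 126 called at 4 months. Across all genes, which are not independent replicates, the log2 differences had a Pearson r of 0.481 between 2 and 4 months, 0.346 between 2 and 8 months and 0.51 between 4 and 8 months (Spearman rho 0.418, 0.29 and 0.373).

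The change of the diabetes effect with age was tested as a difference of differences, in which a shift common to all arrays of an age cancels. From 2 to 8 months the effect grew most for Lcn2 (4.20 ± 0.49; adjusted p = 3.62e-06), Ubd (3.26 ± 0.57), Serpina10 (3.16 ± 0.38), Havcr1 (3.06 ± 0.39) and Cd44 (3.03 ± 0.37). It was lower at 8 than at 2 months for Hspa1a (-2.07 ± 0.49; adjusted p = 0.012), Hspa1b (-1.41 ± 0.33), the coagulation factor gene F5 (-1.32 ± 0.23), Egfl6 (-1.22 ± 0.28) and Hmx2 (-1.10 ± 0.26). In all, 506 genes differed, 392 upward and 114 downward, and the share upward was 77.5%, against 66.6% after quantile normalization (445 and 223) and 65.5% with arrays scaled to one mean and spread (460 and 242). Of 24 tubular injury genes, 19 differed upward (23 adjusted over the list alone), with a median of 1.14 (adjusted p = 0.0133 with an estimated correlation). Of 23 macrophage and dendritic cell genes, 18 did (21 adjusted over the list alone), with a median of 1.25 (adjusted p = 0.0428 with an estimated correlation). The fatty acid synthesis list shifted downward with no single gene passing (0 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0133 with an estimated correlation). These were the 3 of 16 called lists whose call held with an estimated correlation. The count was 329 without diabetic array 3 and 759 without diabetic array 4 of the 8-month group, and 277 in a fit of those 2 ages alone.

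From 4 to 8 months 114 genes differed, 96 upward and 18 downward. The largest were Lcn2 (3.36 ± 0.51), the immunoglobulin genes Igkv9-120 (2.51 ± 0.49), Ighm (2.50 ± 0.31) and Iglv1 (2.49 ± 0.42), and Cd44 (2.50 ± 0.39). Downward were Ier3 (-1.16 ± 0.25), Ngef (-0.87 ± 0.20), Acvr2b (-0.78 ± 0.16), Cbx7 (-0.72 ± 0.16) and Cplx3 (-0.67 ± 0.15). The share upward was 84.2%, against 67.3% after quantile normalization (115 and 56), 69.8% with that done within each age (97 and 42) and 68.5% with arrays scaled to one mean and spread (152 and 70). Of 13 lists called, only tubular injury held with an estimated correlation, with 11 of 24 genes upward (20 adjusted over the list alone), a median of 1.03 and an adjusted p = 0.0225 with an estimated correlation. Macrophage and dendritic cell genes had a median of 1.08, with 11 of 23 upward (21 adjusted over the list alone; adjusted p = 6.02e-26; adjusted p = 0.0622 with an estimated correlation). The count was 64, 74 and 68 without 4-month control 2, 3 and 4, 260 and 172 without 8-month diabetic array 4 and 5, and 14 without 4-month controls 3 and 4 together. With the replicate number as a block it was 19, which kept 4 of the 10 genes named here, and Ier3, Ngef and Cplx3 missed the threshold without at least 1 array.

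From 2 to 4 months limma called 0 genes, while 660 had an unadjusted p under 0.05, and the smallest adjusted p was 0.117. Of 7 lists called, fatty acid synthesis held with an estimated correlation, with a median of -0.30, 0 genes passing (0 adjusted over the list alone), an adjusted p of 3.67e-05 and an adjusted p = 0.00307 with an estimated correlation. A test over all 3 ages at once called 325 genes, 539 without 8-month diabetic array 4.

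Age itself was compared between 8 and 2 months within each group. The mean signal of the arrays was 6.43 to 6.44 at 2 months, 6.02 to 6.04 at 4 months and 6.54 at 8 months, so age and array processing cannot be told apart in these differences. In controls Jchain differed by 5.40 ± 0.34, Igha by 4.37 ± 0.38, Igkv9-120 by 4.04 ± 0.33 and Igkv8-30 by 3.90 ± 0.32, and in diabetic kidneys these stood at 7.26 ± 0.34, 6.09 ± 0.38, 5.70 ± 0.33 and 6.33 ± 0.32. Pam was also higher in both (4.23 ± 0.10 in controls, 4.16 in diabetic kidneys), and Lcn2 differed by 4.89 ± 0.35 in diabetic kidneys and stood at 0.69 in controls (adjusted p = 0.0817). Lower in both groups were the ribosomal gene Rps2 (-3.69 ± 0.05 in controls, -3.58 ± 0.05 in diabetic kidneys), Atp5md (-2.60 ± 0.07 and -2.63 ± 0.07), the chloride channel gene Clcn5 (-2.47 ± 0.08 and -2.63 ± 0.08) and the calcium-binding gene S100g (-2.46 ± 0.11 and -2.62 ± 0.11). Malat1 (-2.55 ± 0.35 in controls, -2.52 in diabetic kidneys) and Slc7a13 (-1.40 in controls, -2.59 ± 0.30 in diabetic kidneys) were also lower in both. The counts were 8292 genes in controls (2758 higher, 5534 lower) and 8584 in diabetic kidneys (3250 higher, 5334 lower), and the median over all genes was -0.14 and -0.11.

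Of the lists, 1 was called with age in controls, oxidative phosphorylation, with 2 of 32 genes higher and 20 lower (2 and 20 adjusted over the list alone), a median of -0.31 and an adjusted p of 0.0337. It had an adjusted p = 0.998 with an estimated correlation. In diabetic kidneys 7 lists were called, and none with an estimated correlation. Macrophage and dendritic cell genes were higher in 21 of 23 cases and lower in 1 (21 and 1 adjusted over the list alone), with a median of 1.42 (adjusted p = 5.49e-10; adjusted p = 0.497 with an estimated correlation). Oxidative phosphorylation had a median of -0.40, with 1 gene higher and 26 lower (1 and 26 adjusted over the list alone; adjusted p = 6.61e-05; adjusted p = 0.886 with an estimated correlation).

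**Figure D3:**
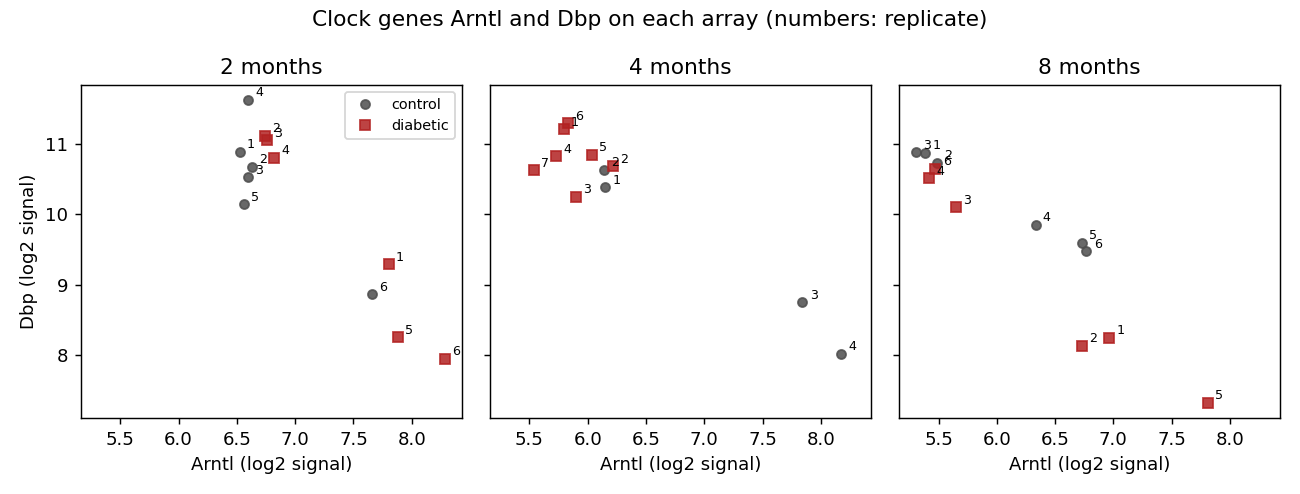
Log2 signal of the clock genes Arntl (horizontal) and Dbp (vertical) on each array, with 1 panel per age; circles are control arrays, squares diabetic arrays, and numbers the replicate. At 4 months controls 3 and 4 stand apart, with Arntl at 7.84 and 8.17 and Dbp at 8.75 and 8.02. At 2 months diabetic 1, 5 and 6 and control 6 stand apart in the same direction.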

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

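The tests on heat-shock genes, on a smaller share of tubule cells, with the clock covariate, on arrays numbered 5 and 6, on splits that part pairs, without 4-month controls 3 and 4, and with quantile normalization within each age were chosen only after the result was seen.

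At 2 months 330 genes were called, and 9 of 100 splits of the same arrays gave as many, with up to 3650 in another split, so chance cannot be excluded by this count. The splits with many calls point to a structure of the samples: of the 6 splits that put all 4 arrays numbered 5 and 6 in one group, 6 gave as many genes, while of 47 that put 2 in each group only the real one did, with 26 at most in the others. Same-numbered arrays were correlated at 2 months, and of the 32 splits that part every pair only the real one gave as many (1 of 32, at most 38 in the others). In the blocked fit 553 genes were called. At 4 months 2 of 100 splits gave as many as the 126 genes (at most 202 in another). At 8 months 1 of 100 gave as many as the 2187 (at most 1020). By these splits chance is an unlikely source of both counts, though at 4 months another split gave more genes than the real one. The splits did not keep 4-month controls 3 and 4, which stood apart, together, so they do not clear the 4-month count of that structure. For the change from 2 to 8 months 3 of 100 splits gave as many as the 506 genes (at most 1016 in another split). For that from 4 to 8 months 1 of 100 gave as many as the 114 genes (at most 2). For the change from 2 to 4 months, with 0 genes, the splits decide nothing, since all 100 must give as many (up to 726). The test over all ages had 325 genes, and 6 of 100 splits that ignore the 2-month pairs gave as many, with up to 1168. Whether chance can be excluded there depends on the structure of the 2-month arrays, which the labels do not state. Among splits that part all pairs only 1 of 100, the real one, gave as many. This held for the test over all ages (at most 19 in the others) and for the change from 2 to 8 months (at most 38). Splits that part all pairs also balance the 2-month arrays 5 and 6 between the groups. They cannot tell pairs from the structure of those arrays. For age 1 of 100 splits gave as many as the 8292 genes in controls (at most 5512) and 1 of 100 as many as the 8584 in diabetic kidneys (at most 6394). For the counts of called lists chance cannot be excluded: 10 of 100 splits gave as many as the 6 lists at 2 months (up to 11), as did 7 of the 32 that part all pairs (up to 7), 10 as many as the 11 at 4 months (up to 12) and 12 as many as the 18 at 8 months (up to 20).

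Some heat-shock genes were higher in diabetic kidneys at 2 months. In a list of 19 written after the result was seen, 6 rose (Hspa1a, Hspa1b, Hspa8, Dnaja1, Dnajb4 and Bag3) and Cryab fell, with a median of 0.27 and quartiles of -0.03 and 0.42. The median was 0.33 in arrays 1 to 4 alone, so it did not rest on the arrays left out. Those were as many in each group, so a batch of them could not by itself make the difference. With the 3'/5' ratio as a covariate it was 0.31, and with the clock covariate 0.25. Each covariate has a slope shared by all ages, and control 6 stood furthest apart in the ratio. An effect with a shared slope thus did not account for the median, but RNA quality and the time of collection stay open. In these 3 runs the 6 genes that rose stayed positive, with Hspa1a at 2.32, 2.19 and 2.06 and Hspa8 at 0.33, 0.27 and 0.25. Handling of the animals or tissue that differed between groups is not described in the labels and stays open, as does diabetes itself. Camera of limma gave the list a p of 9.97e-06, and 0.0761 with an estimated correlation, so the shift of the list as a whole may not exceed that of other genes.

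Many immune and injury genes were higher and some tubule genes lower in diabetic kidneys at 8 months (11 of 26 proximal tubule genes fell and 1 rose), and with an estimated correlation the macrophage (adjusted p = 0.0504) and proximal tubule (0.257) list calls of limma were lost. A smaller share of tubule cells as the only change could raise all other cell types alike, but the endothelial median lay below the macrophage median. The difference was -0.97, with a 95% interval of -1.47 to -0.81 over 10000 resamples of the genes of each list. This interval measures the spread over genes, which are not independent, and not the spread between animals. The tubular injury median of 1.17 was 1.15 with quantile normalization within each age, which argues against the scaling of the arrays as its cause. With the 3'/5' ratio as a covariate it was 1.10. That covariate has a slope shared by all ages, and 2-month control 6 stood furthest apart in it. The beta-actin log2 ratio was 2.56 on that array and 0.78 to 1.05 on the 8-month arrays. The covariate therefore does not settle RNA quality at 8 months. The endothelial and macrophage medians do not exclude a smaller share of tubule cells together with other changes. That, entry or growth of immune cells, altered expression in tubule cells and diabetes itself stay open, since whole-kidney RNA does not separate them. That these changes are biological is a hypothesis, found and tested on the same arrays.

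The 126 genes called at 4 months coincide with a difference of clock genes between arrays. With the clock covariate 116 of the 126 kept at least 0.75 of their log2 difference and 78 were still called. A clock effect with the same slope at all ages thus did not account for the size of most of these differences. At 4 months only controls 3 and 4 had shifted clock genes, so the time of collection is tied to the control group and stays open. Without controls 3 and 4, 78 kept that much and 5 were still called, while the median SE went from 0.122 to 0.156 and 126 kept their direction. With only 2 controls left the influence of controls 3 and 4 cannot be told apart from a diabetes effect and stays open. Diabetes is a biological explanation that may apply, with the 2 of 100 splits above.

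Of 312 groups of values tested for an array far from the others, 21 had one, where chance gives about 1 in 20. At 8 months control 5 stood apart for Havcr1 (7.28, others 6.50 to 6.73), Scd1 (12.72, others 13.37 to 13.67), Agt (9.25), Mcm3 (6.02) and Slc25a37 (9.54). Diabetic 5 did so for Srxn1 (10.15), Adm (8.91) and Aldh1a7 (11.30, others 9.21 to 9.86), diabetic 2 for Aqp4 (9.90), diabetic 3 for Elovl6 (9.99) and control 3 for Miox (13.83). At 2 months control 6 stood apart for Aqp4 (9.21, others 10.21 to 10.74), the beta-actin 3'/5' log2 ratio (2.56, others 0.92 to 1.16) and that of Gapdh (0.99, others -0.16 to -0.01). At the same age diabetic 1 did so for Cdkn1a (10.33, others 8.15 to 8.82) and Npl (11.60), diabetic 6 for Acot7 (9.22), control 5 for Mdk (9.08) and diabetic 5 for the beta-actin ratio (0.81). At 4 months it was diabetic 1 for Akr1c20 (5.99) and control 4 for the beta-actin ratio (0.61).

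Of 128 genes named for a diabetes effect at 1 or more ages, 36 had an effect that differed between ages by the test of the difference itself, 35 of them between 2 and 8 months and 1 between 4 and 8 months alone. Many of the 128 were picked for a large difference or small p at 1 age, which favours a difference between ages. Over all 13004 genes 506 differed between 2 and 8 months. Genes named in the report for their change between ages alone, such as F5, are not among the 128, and some of the 35, such as Lcn2, also differed from 4 to 8 months. The difference, 8 minus 2 months in log2, was upward for Lcn2 (4.20), Ubd (3.26), Serpina10 (3.16), Havcr1 (3.06), Cd44 (3.03), Lyz2 (2.65), Ighm (2.61), Lyz1 (2.46), Cxcl10 (2.30), Cd68 (2.19) and Ms4a7 (2.16). Smaller upward differences were those of Coro1a (1.52), Atf3 (1.35), Mzb1 (1.32), Asns (1.18), Mfsd2a (1.16), Bst2 (0.99), Tagln (0.93), Tgfbi (0.88), Acta2 (0.84), Acot7 (0.79), Oas1a (0.74) and Srxn1 (0.65). Downward ones were those of Hspa1a (-2.07), Hspa1b (-1.41), Egfl6 (-1.22), Hmx2 (-1.10), Nap1l5 (-0.97), Nphs1 (-0.82), Wfdc15b (-0.80), Slc5a2 (-0.69), Egf (-0.63), Slc12a3 (-0.58), Ptpro (-0.54) and Smad7 (-0.46). Cdkn1a differed upward from 4 to 8 months (1.54).

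Probe sets that name no gene or several were not used above. Of the 4000 of both kinds that passed the filter, 31 were called at 2 months, 20 at 4 months and 282 at 8 months, with the largest differences at -3.24, 1.87 and 3.42.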

How the results depend on the processing

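The tests with quantile normalization within each age, arrays scaled to one mean and spread, the clock covariate, the 2-month arrays 5 and 6, 4-month controls 3 and 4 left out together, and the block with an estimated correlation were chosen only after the result was seen. Counts stayed within 1.5 times the value given except where printed here, and the cause was not tested unless named. A stricter filter (60th percentile), which tests fewer genes, gave 68 genes for the change from 4 to 8 months and 214 over all ages. Fits of the groups of a comparison alone have fewer arrays and their own estimate of the spread. They gave 64 at 2 months, 358 at 4 months, 277 from 2 to 8 months and 2 from 2 to 4 months. Array quality weights gave 1296, 942, 1118 and 61 for these, 458 from 4 to 8 months and 1012 over all ages. The replicate block gave 553 at 2 months and 19 from 4 to 8 months, and the 3'/5' covariate 314 from 2 to 8 months. An adjusted p under 0.01, stricter by construction, left 105, 41 and 1248 genes at 2, 4 and 8 months, 178 from 2 to 8 months, 22 from 4 to 8 months and 110 over all ages. Asking for a 2-fold change left 17, 18, 163, 113 and 61, and 115 over all ages, 806 with age in controls and 1023 in diabetic kidneys. From 4 to 8 months 222 were called with arrays scaled to one mean and spread and 36 with the clock covariate. The 2-month arrays 5 and 6 as a batch term gave 696 at 2 months, 854 from 2 to 8 months and 559 over all ages. With arrays 1 to 4 alone it was 7 from 2 to 4 months and 590 over all ages, and with arrays 5 and 6 alone 571 at 2 months. Without 4-month controls 3 and 4 it was 5 at 4 months, 1 from 2 to 4 months and 14 from 4 to 8 months. Lists called at 2 months were 0 with an estimated correlation, 1 with fry and 0 with the block and an estimated correlation, at 4 months 1, 2 and 2, and at 8 months 2 with an estimated correlation and 1 with that and the block. The clock list at 4 months turned from 0.33 to -0.05 with the clock covariate, which is itself built from the clock genes Arntl and Dbp. Pck1 at 8 months, not called, turned from -0.02 to 0.01 with array weights and 0.04 with the 3'/5' covariate. Leaving out each array in turn gave 192 to 515 genes at 2 months, 29 to 135 at 4 months, 1633 to 2329 at 8 months, 329 to 759 from 2 to 8 months, 0 to 2 from 2 to 4 months, 64 to 260 from 4 to 8 months, 229 to 539 over all ages, 7970 to 8403 with age in controls and 8280 to 8615 in diabetic kidneys. Counts beyond 1.5 times were 515 without diabetic array 2, 219, 192 and 512 without controls 1, 2 and 5 at 2 months, and 78, 36 and 29 without diabetic array 5 and controls 3 and 4 at 4 months. From 2 to 8 months it was 329 without 8-month diabetic array 3. From 2 to 4 months it was 1 without 2-month control 4 or 5 or 4-month control 2, and 2 without 2-month control 6. From 4 to 8 months it was 64, 74 and 68 without 4-month controls 2, 3 and 4, and 260 and 172 without 8-month diabetic arrays 4 and 5, and over all ages 539 without 8-month diabetic array 4. In these fits Pck1 at 8 months ran from -0.08 to 0.04 and G6pc from -0.15 to 0.01. No named gene that was called turned direction under any alternative run. Of the named genes called, 16 of 25 at 2 months, 9 of 24 at 4 months and 85 of 96 at 8 months were called whichever array was left out, and 22, 23 and 96 with quantile normalization. Dim signals limit the results to the 13004 of 18193 genes above the filter. A covariate for Xist and a log2 of the value plus a constant were not run, since the arrays show animals of one sex and the values are already on a log2 scale. For the test over all ages a fit of its groups alone is the fit given, and gives no other value.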

Other observations

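The tests of p53 target genes, and the genes of vitamin D, phosphate handling, brown fat and kynurenine metabolism named in this part, were chosen only after the result was seen.

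Cyp27b1, which makes active vitamin D, was higher by 1.60 ± 0.45 at 2 months (adjusted p = 0.0446) and 2.95 ± 0.45 at 8 months, and stood at 1.43 at 4 months (adjusted p = 0.185). Cyp24a1, which degrades it, had means of 9.90 in controls and 8.90 in diabetic kidneys at 2 months and stood at 1.41 and -0.38 at 4 and 8 months, with no call at any age. At 8 months 3 genes of phosphate handling, not tested as a list, fell: Kl, the gene for klotho (-0.46 ± 0.15; adjusted p = 0.0252), and the phosphate transporter genes Slc34a1 (-0.27 ± 0.08; adjusted p = 0.0107) and Slc34a3 (-0.51 ± 0.18; adjusted p = 0.042). The vitamin D receptor gene Vdr stood at -0.26 ± 0.13 (adjusted p = 0.191). Of 3 enzyme genes of kynurenine metabolism, picked by their values and not tested as a list, Kyat3 (-0.57, -0.38 and -0.43) and Aadat (-0.44, -0.40 and -0.42) were called lower at 2, 4 and 8 months. Kmo was called at 4 (-0.57) and 8 months (-0.77) and not at 2 months (-0.18).

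Ucp1, a gene of brown fat, ranged from 5.39 to 9.21 in controls and 4.14 to 6.37 in diabetic kidneys at 4 months (-2.28 ± 0.50), and from 5.22 to 7.99 and 4.69 to 5.21 at 8 months (-2.20 ± 0.46), and was not called at 2 months (-0.16). Cidea, another, stood at -1.18 at 4 months (adjusted p = 0.422) and fell by 2.22 ± 0.52 at 8 months. At 8 months Adipoq stood at 0.85 ± 0.83 (adjusted p = 0.551) and Fabp4 at 0.39 ± 0.18 (adjusted p = 0.136).

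Ccng1 was called higher in diabetic kidneys at 3 ages and Cdkn1a at 2 and 8 months but not at 4 months (0.78; adjusted p = 0.199), and a shift of p53 target genes as a group is a candidate explanation. Of 15 other targets written for the test 12 were measured, 2 of which (Ephx1 and Btg2) another list also holds. Their median was 0.27 at 2 months (3 rose), 0.22 at 4 months (1 rose) and 0.50 at 8 months (6 rose, 1 fell). Camera with an estimated correlation gave a p of 0.00223, 0.0154 and 0.0159 in the fit with limma, so the largest over the ages was 0.0159. Without Ephx1, called at every age before the list was written, 2, 0 and 5 rose, with medians of 0.25, 0.21 and 0.48, and the largest p was 0.0514, at 4 months, so a shift at that age is not shown. The hypothesis was formed on these arrays and may reflect other regulators of the same genes.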
